A study of Homo sapiens with 20 samples.

How the data were processed

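RNA from cell-free saliva supernatant was measured on Affymetrix U133 Plus 2.0 arrays, short-oligonucleotide arrays in which a gene is read by 1 or more probe sets. Per the labels' protocols, the RNA was isolated with a viral RNA kit on magnetic beads, treated with DNase, amplified linearly with RiboAmp, transcribed in vitro with biotin and hybridised in equal amounts. The labels name 10 samples of people with lung cancer and 10 of healthy controls, and call the controls matched without saying how. Each sample is one array. Nothing in the labels ties the number in a control's title to the patient with that number.

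The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes they were made with Affymetrix Expression Console and PLIER. Background correction, scaling between arrays and filters are not given in the sources used here, and no genome build is named, so no coordinates are printed. The arrays do not share a common distribution. On healthy controls 1 to 3 the 10th percentile of intensity lies between 9.79e-05 and 0.000112, against 0.00111 to 0.00143 on the other 17 arrays, and the 75th percentile is 1.47 to 1.51 times the median, against 2.53 to 3.27 times, which leaves open that these arrays were summarised separately. The number of arrays limits the precision.

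The table holds 54675 probe sets, of which 62 control probe sets were set apart and 54613 were tested. Gene symbols came from the platform annotation given with the values. Of the tested probe sets 41091 have 1 symbol, 1801 have several and 11721 are unnamed here, and only those with 1 symbol were named. They cover 19775 genes.

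Intensities were taken as log2(intensity + 16), so a difference on this scale understates the change of dim probe sets. Lung cancer was compared with healthy control with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. No filter was applied. The background level was the 95th percentile of the probe sets of genes of unrelated tissues, a list of genes not expected in saliva. Its mean over the arrays of both groups, used for all of them, was 7.21 on the log2 scale. Array measures and list levels were compared by two-sided permutation tests with 100000 resamples.

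Before the data were examined, 20 gene lists were fixed from general knowledge of saliva, blood cells, airway and tumours. Of their 561 genes 472 were measured, and the list of genes encoded by mitochondrial DNA had none, so 19 lists were tested with camera (preset correlation 0.01, then with an estimated correlation) and fry, and with Fisher's exact test on the share of higher genes, on the probe set of each gene with the highest mean log2 level over all samples. A panel of 7 genes recalled from the study's own publication was among the lists. It was chosen on these samples, so it is not independent evidence. Of these genes 5 are given, and the others were not analysed here.

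The genes named follow a rule fixed at the same time. For each direction it takes the 10 genes with the largest differences among passing probe sets with 1 symbol and a mean above the background level in the higher group. Where fewer pass, the rest are those with the smallest unadjusted p. It adds the panel genes and, for each list, up to 4 members with the highest means or the smallest p. Class prediction used nearest centroids on 50 probe sets chosen again in each of 10 training sets that left out 1 sample of each group.

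On simulated data made from the probe set means and SDs of the same arrays, the test recovered 66 of 100 probe sets shifted by 1 log2 and 89 of 100 shifted by 2 log2, with 10 calls among 54413 unshifted ones. The simulation drew independent normal noise for each probe set, without differences in brightness between arrays, and shifted only brighter probe sets. These counts check the code and do not give the power or error rate on the real arrays. Alternatives covered the pseudocount (1 and 64), quantile normalization, median centring, filters on dim probe sets, variance models, array weights, a rank test, the GAPDH ratio as a covariate, the title number as a block and each sample left out. Scaling by the hybridisation controls and leaving out healthy controls 1 to 3 or 1 to 5 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.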

Results

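Transcript levels in saliva supernatant were compared between 10 people with lung cancer and 10 healthy controls, with 1 array per person. The series addresses whether salivary RNA carries a signature that detects lung cancer. Because nothing states how the people were sampled beyond their group, p-values measure the spread between these arrays.

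The arrays themselves differed in brightness. The mean intensity of the probe sets was 35.2 ± 3.3 (SD, n = 10) in lung cancer and 16.7 ± 7.6 (SD, n = 10) in healthy controls. The groups did not overlap: lung cancer arrays lay between 31.6 and 41.0 and control arrays between 1.72 and 27.4 (permutation test, adjusted p = 1.6e-05). Probe sets with an intensity over 100 numbered 3613 ± 119 in lung cancer and 1815 ± 826 in controls. The control transcripts added at hybridisation did not differ detectably, at 9.46 ± 0.59 and 9.67 ± 1.37 on the log2 scale without a pseudocount (permutation p = 0.661). The median log2 level was 4.07 in lung cancer and 4.08 in controls, close to the floor of 4 set by the pseudocount, so most probe sets were dim on every array. Genes of unrelated tissues, whose transcripts are not expected in saliva, were on average brighter in lung cancer as well, with a level of 4.62 ± 0.07 against 4.33 ± 0.11 (permutation test, adjusted p = 0.00014). The 100 brightest probe sets held 15.1% of the signal in lung cancer and 22.5% in controls (adjusted p = 0.00098). The log2 3' to 5' ratio of GAPDH was 0.46 ± 0.71 in lung cancer and 1.501 ± 1.68 in controls and did not pass (adjusted p = 0.129). That of ACTB was 0.72 ± 1.22 and 1.37 ± 1.85 (adjusted p = 0.423). These means rested in part on 1 array each: without lung cancer 9 they were 0.273 for GAPDH and 0.360 for ACTB in lung cancer, and without healthy control 5 that of ACTB was 0.824 in controls. The 5' probe sets lay far under the pseudocount in lung cancer and controls, at 1.21 and 1.30 for GAPDH and 0.77 and 0.97 for ACTB. Both ratios therefore follow the level of the 3' probe set and do not measure RNA integrity. The mean correlation with the other arrays was 0.767 in lung cancer and 0.669 in controls (adjusted p = 0.034), and 1988 and 2617 probe sets exceeded the array's own background level (adjusted p = 0.024). The first of these 2 calls was lost in 10 of 20 fits that left out 1 array, each time that array was from lung cancer, as well as with a pseudocount of 64 and with the title number as a block, and the second was lost without lung cancer 3 (adjusted p = 0.0525).

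**Figure D1:**
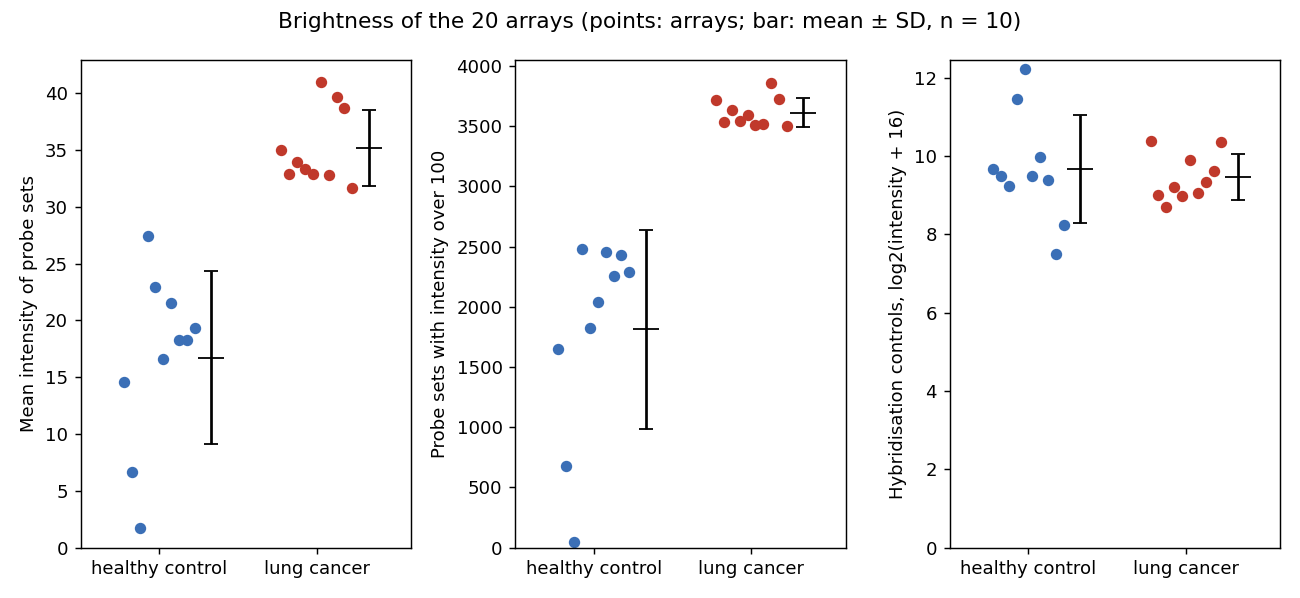
Mean probe set intensity, number of probe sets with an intensity over 100 and mean log2 intensity of the hybridisation controls on each of the 20 arrays, with the mean and SD of each group (n = 10) as a bar. The axis label of the hybridisation controls names a pseudocount of 16, but none was added to these values. In the first panel lung cancer arrays lie between 31.6 and 41.0 and control arrays between 1.72 and 27.4, while the hybridisation controls overlap.

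Probe sets of the same gene hardly shared their level, which bears on every gene named here. Over 6246 genes with at least a pair of probe sets that share few oligonucleotides, the Spearman correlation between them within an array, taken across genes that are not independent replicates, had a median of 0.0046 over the 20 arrays and a range of -0.025 to 0.024. Randomly paired probe sets gave a median of 0.0018. Probe sets differ in affinity, and most pairs lay at the floor, where ranks are noise. The highest correlation that full agreement of the bright probe sets would allow had a median of 0.148. Where a probe set had an intensity over 100, its partner did so in 6.19% (median over arrays) against 5.07% among all pairs, and this share was the higher one on 18 of 20 arrays. With all probe sets included, the median within an array was 0.055 for 71 saliva genes (range -0.152 to 0.311) and 0.024 for all genes. The correlation of a pair over the 20 arrays, a separate measure, had a median of 0.185 for the saliva genes and 0.021 for all genes. The pairs of ACTB and IL1B did follow each other across arrays, with Spearman correlations of 0.962 and 0.495. Among 1547 genes with a higher probe set and at least 2 probe sets, 125 had at least 2 higher (8.08%), where shuffled symbols gave 4.94% to 8.27% over 100 shuffles. A gene name below therefore stands for the named probe set only.

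In lung cancer, 2890 probe sets were higher and 82 lower than in healthy controls, of 54613 tested (limma, adjusted p under the threshold). After quantile normalization, which gives every array the same distribution, 206 were higher and 44 lower. The share of higher among all calls thus went from 97.2% to 82.4%. All of these 206 were among the 2890, and 2841 of the 2890 kept a positive difference, with a median of 0.96 after and 2.05 before that step. In 429 of the 2890 every lung cancer array lay above every control array, where chance would give 0.3 among all tested probe sets. Against the background level pooled over both groups, the mean of the controls was under it in 2656 of the 2890 and that of lung cancer above it in 1602. The background itself differed, with an intensity of 278.8 ± 40.9 in lung cancer and 79.0 ± 55.8 in controls. Against each group's own level, a comparison added after seeing the data, the control mean was under it in 2162 and the lung cancer mean above it in 956. Without healthy controls 1 to 5, the count was 1291 higher and 217 lower.

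The largest difference with a pseudocount of 16 was at the probe set of USP28, a deubiquitinating enzyme, with an intensity of 601.5 ± 185 in lung cancer and 5.55 ± 6.83 in controls. Its log2 difference was 4.83 ± 0.19 (SE, adjusted p = 5.80e-12), and all 10 lung cancer arrays exceeded every control. The next was a probe set of EGFR, the epidermal growth factor receptor, at 983.8 ± 622 against 29.0 ± 60.0 (adjusted p = 7.89e-05). It was bright on 9 lung cancer arrays and on healthy control 1 (197.5, without which the control mean was 10.3), and had an intensity of 28.04 on lung cancer 9. The probe set of BICC1, an RNA-binding protein, had an intensity of 490.3 ± 200.1 against 3.61 in controls (log2 difference 4.59 ± 0.19, adjusted p = 1.28e-11). The antisense transcript PDE11A-AS1, the apolipoprotein gene APOA5, UTP23, NFATC3, a calcium-regulated transcription factor, LOC101928663, DYNLL2, a dynein light chain, and PACSIN2 followed, with log2 differences between 3.63 and 4.31. Control means of these 7 probe sets ranged from 1.58 for APOA5 to 44.0 for PACSIN2. The mean of PACSIN2 in lung cancer, 1537 ± 3581, rested on lung cancer 9, where its intensity was 11713. The control means lay under the pooled background level, so sizes and order depend on the pseudocount and the scaling. With a pseudocount of 1, the difference was 7.14 for USP28, 7.02 for APOA5, 6.69 for BICC1 and 6.05 for the EGFR probe set. With 64, EGFR (3.32) exceeded USP28 (3.21), and under quantile normalization BICC1 (3.65) exceeded USP28 (3.55). Under quantile normalization 9 of these 10 probe sets still passed, and PACSIN2 did not (log2 difference 1.80, adjusted p = 0.306). USP28 has 3 probe sets, BICC1 2 and NFATC3 6, and in each of these genes 1 probe set was higher.

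**Figure D2:**
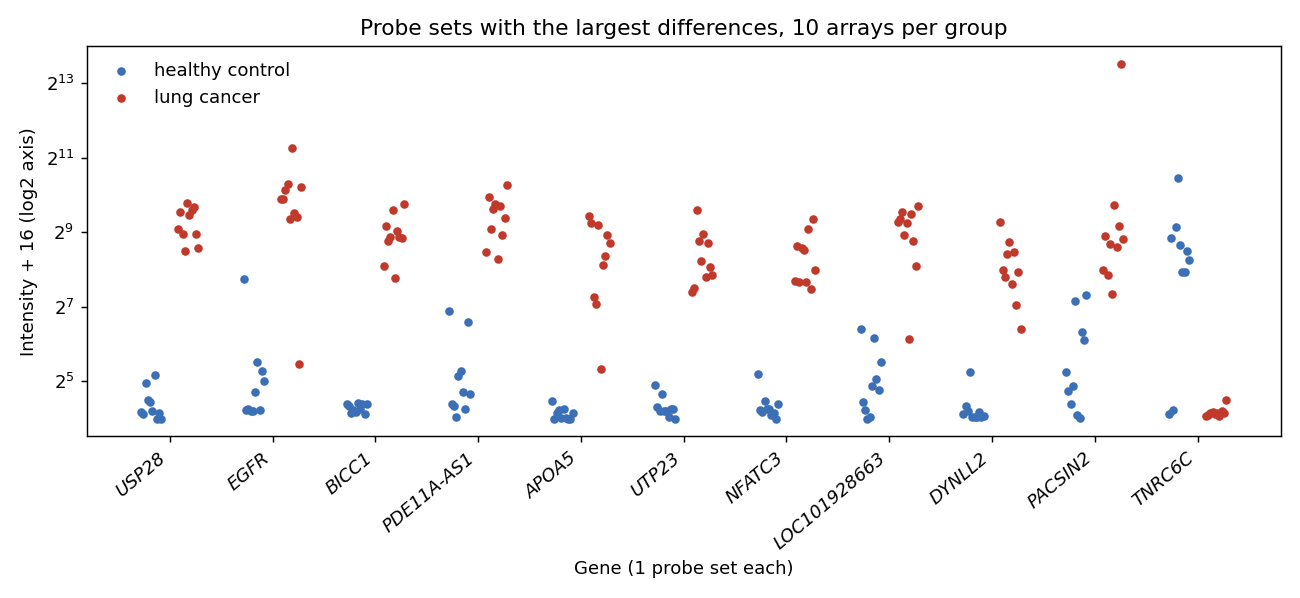
Intensity plus 16, on a log2 axis, of the 10 probe sets with the largest higher differences and of TNRC6C on each array, with 10 arrays per group. USP28 lies near the floor in controls (mean 5.55) and near 601.5 in lung cancer, and TNRC6C is dim on all 10 lung cancer arrays (mean 2.10) and on 2 control arrays.

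Of 61 lower probe sets with 1 symbol, 1 had a mean log2 level above the background level in controls: TNRC6C, a gene of the microRNA silencing machinery. Its intensity was 2.10 ± 1.74 in lung cancer and 385.4 ± 391 in controls (log2 difference -3.63 ± 0.63, adjusted p = 0.00137). On 8 of the 10 control arrays it was at least 227, and on healthy controls 1 and 3 it was 1.29 and 2.87. The gene has 7 probe sets, of which this 1 was lower. The other genes given for that direction also had control means above the background level, did not pass and were taken by their unadjusted p. They were KRT4, a mucosal keratin (24.998 ± 38.8 against 575.6 ± 1281, log2 difference -2.43 ± 0.74, adjusted p = 0.065), KRT13, its partner (57.6 against 953.9, adjusted p = 0.211), the cornified envelope genes SPRR1A (38.6 against 455.6, adjusted p = 0.093) and SPRR3 (144.9 against 2337, adjusted p = 0.250), the protease inhibitor CSTA (adjusted p = 0.503), RPS28, RPL10A and RPL41 (adjusted p = 0.229, 0.294 and 0.375), and the receptor EPHA10 (65.3 against 204.3, adjusted p = 0.160), of whose 3 probe sets another was higher. The control means of KRT4 and KRT13 rested on healthy control 4 (4182 and 7864) and were 174.9 and 186.1 without it. KRT4 had a median of 104.0 in controls and 7.66 in lung cancer, where its mean was 14.3 without lung cancer 3. The control mean of SPRR3 was 1450 without healthy control 5, and its lung cancer mean was 89.0 without lung cancer 3. In fits that left out 1 array KRT4 passed in 3 of 20 and SPRR1A in 1. Under quantile normalization KRT4 and EPHA10 passed, with adjusted p of 0.043 and 0.0017.

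For the panel of the study's publication, chosen on these samples, the 5 genes given here all had higher means in lung cancer. All 5 passed adjusted over the list alone, which is not independent evidence, and 2 over all probe sets tested. Over the list alone 2 passed under quantile normalization and without healthy controls 1 to 3 or 1 to 5. With the title number as a block or hybridisation control scaling 3 passed, and 4 with array weights or the GAPDH ratio as a covariate. Among probe sets above background EGFR and LZTS1 passed. FGF19, GREB1 and CCNI had mean log2 levels over all arrays under the background level, so they were not tested there. In fits that left out 1 array, 4 passed over the list alone in 13 of 20 and 5 in the others, and over all probe sets 2 to 4 passed. GREB1 gained its call in 3 of these fits and CCNI in 1, and both passed without lung cancer 6. The probe set of EGFR with the highest mean log2 level over all arrays, which is not the one described above, had an intensity of 441.5 ± 200.9 against 62.3 ± 63.2 (log2 difference 2.97 ± 0.47, adjusted p = 0.00065) and separated the groups fully, with an area under the curve of 1. FGF19, a fibroblast growth factor, had 213.3 ± 196.6 against 1.37 ± 1.70 (log2 difference 2.95 ± 0.58, adjusted p = 0.0036, area 0.82). GREB1, an oestrogen-responsive gene, the cyclin gene CCNI and LZTS1, a leucine zipper tumour suppressor candidate, did not pass over all probe sets, with adjusted p of 0.095, 0.215 and 0.364 and areas of 0.80, 0.77 and 0.79. Probe sets of one panel gene disagreed. Of 9 EGFR probe sets 3 were higher and 4 had means of at most 5.13 in both groups. For CCNI, a probe set other than the one tested in the panel was higher (124.6 against 0.72, adjusted p = 0.00025), while the remaining one was dim in both groups (3.91 against 15.6, or 6.49 without healthy control 4, and 2.06 in lung cancer without lung cancer 9). Of 7 LZTS1 probe sets, the one tested in the panel alone had a mean above 9.94 in lung cancer. Under quantile normalization FGF19 passed (adjusted p = 0.044) and that EGFR probe set with the highest mean log2 level did not (log2 difference 1.597, adjusted p = 0.184).

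Among the gene lists, 4 of 19 passed camera with the preset correlation. Ribosomal protein genes lay lower in lung cancer relative to other genes, with a mean log2 difference of -0.93 over 53 genes (adjusted p = 1.07e-11, and adjusted p = 0.558 with an estimated correlation). RPL18 was higher (adjusted p = 0.011), RPL36 lower (adjusted p = 0.020) and 51 did not pass. Under quantile normalization RPL36 passed (adjusted p = 0.047) and RPL18 did not (adjusted p = 0.813). Oxidative phosphorylation genes lay lower (mean -0.30 over 32 genes, adjusted p = 0.00018, and 0.558 with an estimated correlation). Their 1 higher gene was COX6A1, a call lost in 13 of 20 fits that left out 1 array and turned to -0.31 under quantile normalization. Saliva reference transcripts, a set of RNAs known to be abundant in saliva, lay lower as well (mean -0.83 over 13 genes, none passing singly, adjusted p = 0.0045, and 0.558 with an estimated correlation), and their direction turned with the GAPDH ratio as a covariate (0.33). That ratio follows the GAPDH level and GAPDH is in this list, so the turn can be built in. No fit with this covariate tests RNA quality. The panel lay higher (adjusted p = 0.0019, and 0.231 with an estimated correlation). With an estimated correlation 0 of the 19 lists passed, and 1 had an unadjusted p under 0.05. The sizes of the 3 lower lists rested in part on healthy controls 4 and 5. Without healthy control 4 the means were -0.56 for ribosomal protein, -0.09 for oxidative phosphorylation and -0.55 for saliva reference genes, and without healthy control 5 the last 2 were -0.14 and -0.45. All 3 passed camera with the preset correlation of 0.01 in each fit that left out 1 array. Their estimated correlations were far higher, at 0.778, 0.452 and 0.740 in the same order, so these passes rest on the preset value. Among probe sets above background, the ribosomal protein mean was positive (0.755), where the median over the probe sets kept was 1.80. Without healthy controls 1 to 5, a setting chosen after seeing the data, the ribosomal protein list alone still passed (mean -0.143), and the panel (adjusted p = 0.0755), the oxidative phosphorylation list (mean 0.102, adjusted p = 0.444) and the saliva reference list (mean -0.015, adjusted p = 0.313) did not. With the GAPDH ratio as a covariate the means were 0.027 for ribosomal protein genes, which still lay lower relative to other genes (adjusted p = 0.0049), and 0.212 for oxidative phosphorylation genes, which did not pass (adjusted p = 0.661). Under quantile normalization 4 more lists passed with the preset correlation, each lower in lung cancer: oral squamous epithelium (mean -1.13, adjusted p = 5.86e-06), neutrophil (-0.85, 8.81e-05), salivary gland secretory (-0.73, 0.00015) and hypoxia genes (-0.56, 0.00054). With an estimated correlation, a setting added after seeing the data, their adjusted p were 0.205, 0.317, 0.205 and 0.205. By fry, which asks whether a list's genes move one way on balance and not relative to other genes, 5 lists passed, each with a higher mean in lung cancer. They were the panel (adjusted p = 0.00012), genes of unrelated tissues (0.00035), proliferation (0.0024), B and plasma cells (0.0033) and smoking-responsive genes (0.0037), while the ribosomal protein, oxidative phosphorylation and saliva reference lists had 0.232, 0.356 and 0.409. The level of the ribosomal protein list varied more among controls (6.22 ± 1.69) than in lung cancer (5.29 ± 0.65), as did the GAPDH ratio given above.

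Genes of saliva cells and glands mostly did not pass. In the oral squamous epithelium list 6 of 33 genes were higher, 1 lower and 26 did not pass, and the list did not pass camera (mean -0.27, unadjusted p = 0.045, adjusted p = 0.144). It passed in 1 of 20 fits that left out 1 array (adjusted p = 0.014 without healthy control 1), and its mean was -0.067 without healthy control 4 (adjusted p = 0.393). KRT76, a keratin of the palate, was higher (554.5 ± 147 against 139.0, adjusted p = 0.0028), as was EMP1 (262.5 against 71.9, adjusted p = 0.0025), while neither passed under quantile normalization (log2 differences 0.78 and 0.77, adjusted p = 0.296 and 0.497). The SPRR3 probe set with the highest mean log2 level, another than the one given above, had 253.7 against 1075 and did not pass (adjusted p = 0.412). The lower gene, named after its values were seen, was TGM3, a transglutaminase of the cornified envelope (1.47 against 185.1, adjusted p = 0.025). Among 24 secretory genes of salivary glands 1 was higher, CA6, a secreted carbonic anhydrase (236.6 against 63.6, adjusted p = 0.027), and its call was lost in 4 of 20 fits that left out 1 array (without healthy control 1, 2 or 6 or lung cancer 8) and its direction turned under quantile normalization (-0.07). The mucin gene MUC7 had 17.6 against 236.2 (adjusted p = 0.326), and the proline-rich protein gene PRB1 had 169.3 against 3137, the latter from healthy control 4 at 30720. Without healthy control 4 the control means were 144.2 for MUC7, 72.6 for PRB1, 38.4 for CA6, 46.4 for EMP1 and 101.9 for TGM3, and without lung cancer 3 the lung cancer mean of the SPRR3 probe set in this paragraph was 168.7. The salivary gland list had a mean of -0.144 and an adjusted p of 0.058. It passed in 7 of 20 fits that left out 1 array, and its mean turned positive without healthy control 4 (0.039, adjusted p = 0.402). Of 27 neutrophil genes 3 were higher and 24 did not pass (list mean -0.115, adjusted p = 0.299). The list passed in 1 of 20 fits that left out 1 array (mean -0.317, adjusted p = 0.0095 without lung cancer 9), and its mean turned positive without healthy control 5 (0.118, adjusted p = 0.822). The higher genes were the receptor genes CSF3R (163.8 against 3.62, adjusted p = 0.0010), FCGR2A (45.6 against 8.89, or 4.44 without healthy control 1, adjusted p = 0.0066) and TREM1 (443.9 against 301.3, adjusted p = 0.033). The control mean of TREM1 rested on healthy control 5 (2445) and was 63.1 without it. TREM1 lost its call in 13 of 20 fits that left out 1 array, and CSF3R alone of these passed under quantile normalization (adjusted p = 0.033). The abundant calprotectin gene S100A8 had 918.9 ± 1459 against 1406 and did not pass (adjusted p = 0.854), and its lung cancer mean was 483.2 without lung cancer 9.

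Other lists held few higher genes and no lower one. Over all 19775 genes 9.89% were higher, and 0 of the 19 lists passed Fisher's exact test of their share of higher genes against that of other genes. The 2 lists with an unadjusted p under 0.05 were B and plasma cells and smoking-responsive genes, with odds ratios of 4.57 and 3.43 (adjusted p = 0.164 for each). Higher genes numbered 5 of 15 for B and plasma cells, among them BANK1 (727.7 against 240.5, adjusted p = 0.010) and IGLL5. They numbered 6 of 22 for airway genes that respond to smoking, among them the detoxifying enzymes CBR1 (165.6 against 3.42, or 1.34 without healthy control 1, adjusted p = 0.00065), ADH7 (334.4 against 61.5, or 39.6 without healthy control 10, adjusted p = 0.0011) and ALDH3A1 (adjusted p = 0.042, a call lost in 16 of 20 fits that left out 1 array). For proliferation there were 3 of 28, with NUSAP1, the kinase AURKA and, named after its value was seen, MCM5 (adjusted p = 0.0011, 0.013 and 0.026), and for lung and airway epithelium 2 of 16, AGER and CFAP45 (adjusted p = 0.025 and 0.021, the former at 0.0503 without healthy control 2). For lung cancer drivers there were 2 of 27, MYC (638.1 ± 217 against 201.9, adjusted p = 0.015) and FGFR4 (adjusted p = 0.0079). The interferon list had 2 of 28, EPSTI1 and IRF9, and the NF-kB list 2 of 31, DUSP1 and NFKBIA. Monocytes had 1 of 16, AIF1, T and NK cells 1 of 20, CD5, hypoxia 1 of 23, ERO1A, and red cells 0 of 8. Camera adjusted p for these lists, in the order B cell, smoking, proliferation, airway, driver, interferon, NF-kB, monocyte, T cell, hypoxia and red cell, were 0.383, 0.351, 0.383, 0.782, 0.441, 0.810, 0.441, 0.441, 0.782, 0.383 and 0.149. Genes of unrelated tissues were higher in 9 of 51 (camera adjusted p = 0.383). They included the olfactory receptor genes OR2H1 (1032 ± 311 against 261.7, adjusted p = 0.012) and OR7A5, the skeletal muscle gene TNNT3 (224.2 against 26.6, adjusted p = 0.00028) and the astrocyte gene GFAP (489.6 against 179.1, adjusted p = 0.030, a call lost in 6 of 20 fits that left out 1 array). Under quantile normalization, of the genes in this paragraph other than MCM5, CBR1 alone passed (adjusted p = 0.030), and IRF9 turned its direction (-0.08). The value of MCM5 in that setting is not given here.

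The levels of the neutrophil and ribosomal protein lists went together over the 20 arrays, with Pearson's r = 0.774 (permutation p = 0.00049, adjusted p = 0.00098) and Spearman's rho = 0.916 (permutation p = 1e-05, adjusted p = 2e-05, the smallest the resamples can give). Without healthy control 5 and lung cancer 9, the arrays farthest from the median of the neutrophil level, r was 0.860. Within lung cancer rho was 0.927 (permutation p = 0.00037) and within controls 0.964 (permutation p = 7e-05). These are 4 relations of 1 family. Other lists, compared after seeing the data, moved on the same arrays. Spearman's rho with the neutrophil and ribosomal protein levels was 0.860 and 0.880 for oral squamous epithelium, 0.799 and 0.746 for salivary gland secretory genes and 0.925 and 0.949 for saliva reference transcripts, while genes of unrelated tissues gave -0.080 and -0.325 (adjusted p = 0.806 and 0.206). For oral squamous epithelium and the neutrophil list it was 0.806 within lung cancer (adjusted p = 0.0124) and 0.927 within controls (adjusted p = 0.000764). For salivary gland secretory genes and the neutrophil list it was 0.624 within lung cancer, which did not pass (permutation test, adjusted p = 0.0827), and 0.7455 within controls (adjusted p = 0.0277).

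**Figure D3:**
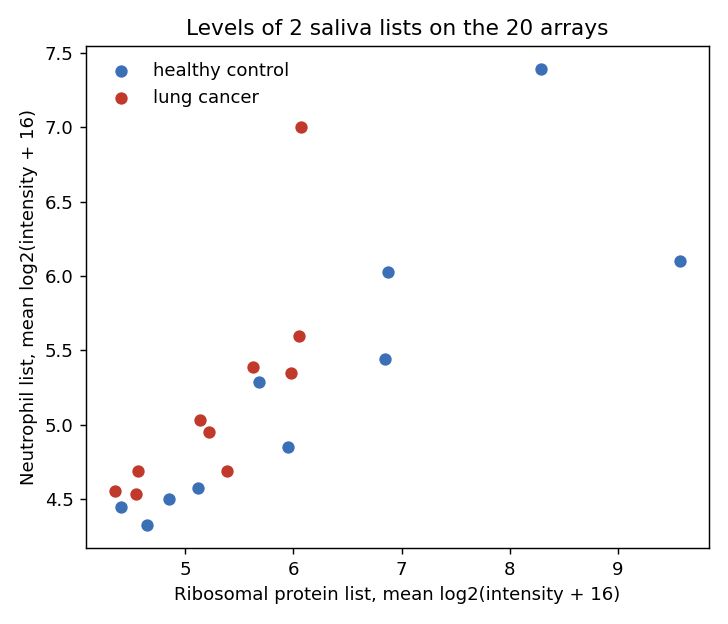
Mean log2(intensity + 16) of the ribosomal protein list on the horizontal axis and of the neutrophil list on the vertical axis, 1 point per array and colours by group. Both levels go together over the 20 arrays (rho = 0.916). Arrays of both groups lie at the upper end of the neutrophil axis. The highest ribosomal protein levels are those of controls, with 9.57 on healthy control 4, and lung cancer reaches at most 6.07, on lung cancer 9.

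Class prediction placed 20 of 20 left-out arrays in their own group with 50 probe sets chosen without them. Other splits of the 20 arrays reached at most 16, with a median of 11 over the splits drawn. With quantile normalization 19 of 20 were placed in their own group. Mean intensity alone also separated the groups without overlap, as given above.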

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

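The 2 tests of the neutrophil genes were written before their results were seen, and the tests of IL1B alone and of more neutrophils alone were chosen only after their values were seen. A single array stood far from its group in 43 of 216 group values, where chance alone gives about 10.8. Each number below is the gap between that array and its nearest neighbour as a share of the group's range.

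Lung cancer 9 accounted for 12 of the 43. It was high in the log2 3' to 5' ratios of GAPDH (2.17, gap 0.516) and ACTB (3.95, gap 0.717) and in the share of signal in the 100 brightest probe sets (20.5%, gap 0.651). Its levels were high for the neutrophil (gap 0.568), monocyte (gap 0.585), interferon (gap 0.688) and hypoxia lists (gap 0.562) and the saliva reference transcripts (gap 0.502), and for PACSIN2 (gap 0.615) and GAPDH (gap 0.640). It was low for the EGFR probe set with the largest difference (gap 0.670) and ALDH3A1 (gap 0.739).

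Lung cancer 6 accounted for 13. Its mean correlation with the other arrays was 0.737 (gap 0.551). It was high in the red cell list (gap 0.476), CD3G (gap 0.518), CENPF (gap 0.603) and OAS3 (gap 0.629). It was low in the lung and airway list (gap 0.593), LOC101928663 (gap 0.549), AIF1 (gap 0.570), AGER (gap 0.608), EPSTI1 (gap 0.554), DUSP1 (gap 0.631), ENO1 (gap 0.670) and PDK1 (gap 0.587). Lung cancer 8 was high in the proliferation list (gap 0.580), lung cancer 10 in TNRC6C (gap 0.673), and lung cancer 7 was low in ATP5F1E (gap 0.669).

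Healthy control 1 was high in that EGFR probe set (gap 0.628), NFATC3 (gap 0.611), FCGR2A (gap 0.681) and CBR1 (gap 0.841). Healthy control 3 was low in its mean correlation with the other arrays (0.319, gap 0.502) and in CSF1R (gap 0.488), BANK1 (gap 0.507) and GBP1 (gap 0.622). Healthy control 4 was high in KRT13 (gap 0.472), PRB1 (gap 0.673), CA6 (gap 0.486) and DYNLL2 (gap 0.761). Healthy control 5 was high in the ACTB ratio (6.33, gap 0.729), healthy control 8 in NUSAP1 (gap 0.632) and healthy control 9 in CA1 (gap 0.474).

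The neutrophil list and IL1B, an inflammatory cytokine gene singled out after its values were seen, stood far above their usual level on few arrays. IL1B had an intensity of 24920 on lung cancer 9, 7479 on lung cancer 3, 5635 on healthy control 5 and 4449 on lung cancer 5, against medians of 187.8 in lung cancer and 54.5 in controls. For the neutrophil list, the 5 arrays with the highest level came from both groups, with healthy control 5 highest (permutation p of the difference 0.771), so lung cancer cannot be the whole source of high levels. For IL1B, which was over 1000 on 3 lung cancer arrays and 1 control and over 100 on all 10 lung cancer arrays and 4 controls, it stays open (log2 difference 2.63, interval 0.16 to 5.10, p = 0.0378, limma adjusted p = 0.333). A varying amount of saliva RNA between samples may contribute, since the neutrophil and ribosomal protein lists went together with a Spearman correlation of 0.916. Neutrophils express ribosomal protein genes too, but more neutrophils alone would not raise the keratins of the oral squamous epithelium list, which neutrophils do not express. That list followed the neutrophil list with a Spearman correlation of 0.860 (interval 0.67 to 0.93), 0.806 within lung cancer and 0.927 within controls. The cells behind both lists can vary together, so this relation cannot exclude more neutrophils as the source of the high neutrophil levels. Whether more neutrophils added to the level of single arrays stays open, as on lung cancer 9, which ranked 2 of 20 by neutrophil level and 7 by oral squamous epithelium level.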

How the results depend on the processing

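Scaling by the hybridisation controls and leaving out healthy controls 1 to 3 or 1 to 5 were chosen after seeing the data. The direction of the difference in calls, more higher than lower, held under every alternative run, while the counts moved. Against 2890 higher and 82 lower probe sets, 5 panel genes and 4 lists, quantile normalization gave 206, 44, 2 and 8. Restricting to probe sets above background left 1678 to test and gave 1459, 5, 2 and 2, with a median log2 difference of 1.80. Most of the probe sets kept were thus brighter in lung cancer. The panel probe sets of FGF19, GREB1 and CCNI were not tested there. Restricting to the brighter part of the probe sets gave 138 lower and 7 lists. With the GAPDH ratio as a covariate there were 1867 higher and 2 lists. Hybridisation control scaling gave 1444 higher, 31 lower and 3 panel genes. With fewer samples, leaving out healthy controls 1 to 3 gave 1881 higher, 177 lower and 2 panel genes, and leaving out 1 to 5 gave 1291, 217, 2 and 1 list. Lower probe sets numbered 173 with a pseudocount of 1, 45 with 64 and 190 by the Wilcoxon test. With an estimated correlation 0 lists passed, also after quantile normalization (0 lists), a combination added after seeing the data. Quantile normalization reversed CA6 (-0.074), IRF9 (-0.076) and COX6A1 (-0.310), and the GAPDH covariate reversed the saliva reference transcripts (0.329). That covariate follows the level of GAPDH, a member of that list, so this turn does not test RNA quality. Further calls of named probe sets were lost: 27 under quantile normalization, 15 with hybridisation control scaling and 9 with the title number as a block. With the GAPDH covariate 8 were lost, without healthy controls 1 to 3 it was 9, and without 1 to 5 it was 16. The cause of these changes was not tested. Leaving out 1 array at a time gave 2281 to 2987 higher, 57 to 116 lower and 2 to 4 passing array measures, 2 without lung cancer 3. Class prediction stayed at 19 or 20 of 20, and at 15 of 15 without healthy controls 1 to 5.

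The title number as a block gave 1978 higher, 36 lower, 3 panel genes and 6 lists. Samples with the same number did not deviate together: deviations correlated above 0.1 in 1 of 10 pairs (range -0.153 to 0.102), and 0 lung cancer samples correlated best with their own number. Matched people need not show such a correlation, so whether the numbers pair the samples stays open. Signal over background limits the results, since 2656 of the higher probe sets had control means under the pooled background level.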

Other observations

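The tests of brightness, of healthy controls 1 to 3 and of healthy controls 1 to 5 were chosen only after the result was seen, as were the highest correlation that the floor allows and the part of the brightness test that looks at how many higher calls were left.

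Some probe sets were bright on arrays of both groups. That of CDKN2A, a cell cycle inhibitor, had an intensity of 7047 ± 355 in lung cancer and 4063 ± 1705 in controls, AP4E1 had 4635 ± 181 and 3207 ± 1100, PPM1H 4901 ± 275 and 2900 ± 1259, and ARF6 4277 ± 442 and 2433 ± 1178. They were chosen after their values were seen. Intensities of different probe sets depend on their affinity and do not rank transcripts by amount.

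The source of this shared signal stays open. For transcripts of saliva cells and glands, the level of their lists above that of genes of unrelated tissues was 0.347 on the median array. At least 1 was written down beforehand for this source and under 0.5 against it, so the value met the bound against. However, the lists are read by different probe sets, whose affinity can set this offset. This limit was raised after the value was seen, and with it the test decides nothing. With the same limit, 7 of the 1000 genes with the highest mean log2 level were saliva genes, where 7.5 would be expected. The offset ranged from -0.48 to 3.38 over the arrays, with a median of 0.12 in lung cancer and 0.98 in controls, a difference that was not tested. Products that do not follow transcripts, such as by-products of amplification, are a candidate explanation: the correlation of probe sets of the same gene was 0.0046, where under 0.1 was written down beforehand for this source and over 0.3 against it. Because most pairs lie at the floor, full agreement of the bright ones would give a median of 0.148, so the bound against it could not be reached and this source cannot be told apart from others. Fragmented RNA, of which each probe set sees another piece, could lower this correlation too and was not tested.

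The excess of higher over lower probe sets in lung cancer was weighed against technical sources. In 100 splits of the 20 arrays, 1 split, the real one, gave as many calls (2972), and the highest of the others gave 1. None of the other splits drawn thus came near the real count. The real split also separates the arrays by mean intensity without overlap. The count of calls therefore cannot tell a difference in brightness from one in transcripts. Without healthy controls 1 to 3, whose low values look separately processed, the higher calls were 10.6 times the lower ones (1881 and 177). Without healthy controls 1 to 5 they were 5.95 times (1291 and 217). An excess remained, which argues against these arrays as the whole source, but it was smaller, with fewer samples. The controls left were still dimmer than every lung cancer array, so these fits do not separate the excess from brightness. After quantile normalization the ratio was 4.68, which taken alone would argue against brighter arrays as the whole source, but 206 of 2890 higher calls were left and the groups do not overlap in mean intensity, so brighter arrays and lung cancer cannot be told apart. Signal that does not come from human transcripts may contribute: of 27 bacterial control probe sets none passed (lowest adjusted p = 0.108) and the median difference was -0.02, a bound written beforehand as evidence against it, but with 5.29% of all probe sets higher only 1.43 of 27 would be expected to rise, so that bound was wrongly chosen and the test leaves this open.

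Among those bacterial controls, PheX-M had an intensity of 29.3 ± 37.0 in lung cancer and 0.70 ± 0.79 in controls, with 8 of 10 lung cancer arrays above every control, and PheX-3 had 35.8 ± 43.0 against 3.03 ± 5.75 (adjusted p = 0.108 for each).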
